A study of Mus musculus with 4 samples.

How the data were processed

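RNA of hearts from 4-day-old Wtapflox/flox (control) and Wtap-CKO (knockout) mice was pooled per genotype, from 7 and 8 mice and 300 µg in all according to the series' design text, fragmented to about 100 nt, incubated with an anti-m6A antibody for 2 h and sequenced as IP and input libraries with 150-base paired reads, per the labels' protocols. Samples were grouped by the genotype and antibody labels; titles of the knockout samples carry another abbreviation than the genotype label. Each of the 4 groups held 1 library.

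The authors called peaks with exomePeak 2.16.0 in each IP against its own input at a q threshold of 0.05, per the series' design text, and deposited 1 peak list per genotype. The submitters' processing notes also name fastp 0.19.11, BWA 0.7.12, HOMER 4.9.1 and build GRCm39, without roles; how reads were assigned to copies of a gene or scaled between IP and input is not given in the sources used here. Each list gives exonic blocks, the strand of the annotated gene and an Ensembl gene ID. The deposited score column holds the p-value of each peak by the authors' caller. The authors' log10 p and log10 q values were read as a score, since they reach minus infinity (203 control and 197 knockout peaks). The authors' fold enrichment is a linear ratio of IP over input per peak, between 1.14 and 148 in the control list and 1.12 and 193 in the knockout list; it was used to describe and rank peaks within a list. All listed q values were at or under 0.05 within rounding (largest log10 q -1.31 and -1.30). The lists hold no read counts, so the depth of each library was unknown and no correction for depth could be made.

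Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. A peak was called shared when at least 1 exonic base overlapped a peak of the other list on the same strand. Genes were compared by Ensembl ID. In 7.74% of control and 7.64% of knockout peaks, a peak of a gene on the other strand overlapped in the same list, and antisense genes then cannot be told apart. Shares have exact (Clopper-Pearson) 95% intervals, and medians of fold have distribution-free 95% intervals by order statistics. Both cover counting error only and take peaks as independent, also those of the same gene. The difference in log2 ratio of log10 p between gene groups has an interval from 2000 bootstrap resamples of genes. With 1 pooled pair per genotype no p-value was computed.

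The 24 gene lists and the rule for named genes were fixed before the data were examined. The rule named Wtap and the m6A list, Mef2a, Mef2c, Gata4, Nkx2-5, Tbx5, Myh6, Myh7, Nppa and Nppb; for shared, control-only and knockout-only peaks, the 8 genes with the largest fold among the 25% of smallest q; per list, up to 2 control-only and 2 knockout-only members with most peaks; and up to 2 members per list with most peaks in both lists together. It took 152 genes, and genes named beyond it are said to be chosen after their values were seen. Symbols were matched to a RefSeq table of GRCm38.p6, which served for synonyms and gene types only (11471 symbols matched); 88.4% of 38319 peaks of protein-coding genes lay outside the span of that gene there, so none of its coordinates were used.

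For each list, the number of control-only and knockout-only genes was set among 10000 random lists of the same size. The planned matching on exonic length needs an annotation of the files' build, which was not used here, so random lists were matched on the number of peaks in both lists together. Strong peaks (q at or under 1e-10, with 1e-05 and 1e-20 as alternatives), the random lists matched on strong peaks per gene, the joined lists (4 heart muscle lists, with all 7 and the 6 without fatty acid oxidation as alternatives), the counts by gene or without the gene with most strong single-list peaks, the joined lists without Ttn and the position of single-list peaks relative to shared ones were added after the data were seen. The overlap code was tested on 19795 simulated peaks that overlapped no other peak of their list. It found 100% of kept peaks, which were shifted slightly, and 0% of those moved to a separate sequence. The test does not show how the rule treats peaks that lie close together. In a simulated list with planted single-list genes 0% of random lists had as many, and 2 of 100 lists without any fell under 5%.

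Alternatives were q at or under 0.01 and 0.001, folds of at least 2 and 4, merged peaks, overlaps of 50% of the shorter or of both peaks, overlap without strand, whole spans, the same number of peaks from each list (15574, smallest q first), 1 peak per gene, protein-coding genes only and random lists without matching. Transcript regions and the m6A motif, planned with their alternatives, were not analysed here because they need the genome and annotation of GRCm39. Results for some single genes are not reported here.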

Results

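N6-methyladenosine (m6A) on RNA was mapped by MeRIP-seq, in which fragmented RNA is pulled down with an anti-m6A antibody and sequenced beside the input RNA, in hearts of 4-day-old control (Wtapflox/flox) and knockout (Wtap-CKO) mice. Each genotype had 1 immunoprecipitation (IP) and 1 input library, made from RNA pooled from 7 control and 8 knockout mice, so the 4 libraries held no replicates. Differences between the lists therefore have no replicate check, no test between genotypes was possible, and the exact 95% intervals given with shares cover counting error only. The peak lists carry no read totals, so the depth of each library was unknown. Positions are those of mouse build GRCm39, and whether a peak lay in a coding exon or a UTR was not analysed here.

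Wtap, which encodes a regulatory subunit of the m6A methyltransferase complex and is the targeted gene, carried 3 peaks in the control list and 4 in the knockout list on chromosome 17. The control peak at 13186370 to 13186938 had a fold enrichment of 9.90 and overlapped a knockout peak at 13186460 to 13186908 with a fold of 4.58. The control peak at 13193539 to 13193837 (fold 11.8) overlapped a knockout peak at 13193479 to 13193957 (fold 28.1). The control peak at 13194136 to 13199722 spanned 2 exonic blocks, while the overlapping knockout peak at 13194166 to 13194316 had 1 block. A knockout peak at 13210995 to 13211114 (log10 q -1.80) had no counterpart in the control list. A fold is the IP over input value that the authors' caller gave to a peak in a list made separately for each genotype, so it is no transcript level, and these peaks do not check the deletion.

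The first question was how many m6A peaks were called in each genotype. The control list held 20766 peaks in 10734 genes and covered 7.31 Mb, and the knockout list held 21179 peaks in 10904 genes and covered 6.90 Mb. Ahnak, named after its values were seen, had the most peaks of any gene in the knockout list (21). The median peak was 270 bases wide in the control list and 241 bases wide in the knockout list. Within the control list, the median fold was 7.22 (95% interval by order statistics 7.03 to 7.22, quartiles 3.93 and 12.7). Within the knockout list, it was 7.03 (6.99 to 7.19, quartiles 3.84 and 13.1). The knockout list held 413 peaks more than the control list, but among peaks with a fold of at least 4 the difference, knockout minus control, was -5.

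The second question was which peaks the genotypes shared. Of the control peaks, 15793 (76.1%, 75.5 to 76.6) overlapped a knockout peak by at least 1 exonic base on the same strand, and 4973 (23.9%, 23.4 to 24.5) did not. In the knockout list, 15999 peaks were shared and 5180 (24.5%, 23.9 to 25%) were not. Among the 25% of peaks with the smallest q in each class, shared peaks with a large fold in both lists included those of Cdc73, which encodes a subunit of the PAF1 transcription elongation complex (chromosome 1, 143578242 to 143578601 in both lists, fold 58.5 in the control and 63.8 in the knockout), Epm2aip1 (56.1 and 60.0), Klc3, a kinesin light chain gene (49.7 and 149), and Smarcd3, which encodes a BAF chromatin remodelling subunit of heart and skeletal muscle (65.8 and 48.8). Among control-only peaks of that kind, the largest folds were those of Cdh20, a cadherin gene (chromosome 1, 104921859 to 104922308, fold 89.0), Ybey (61.8), the sodium channel gene Scn10a (52.5), Ahrr (51.3), Exo1 (48.1) and Kcnj3, which encodes a subunit of the acetylcholine-gated potassium channel (46.5). Among knockout-only peaks of that kind, they were those of the predicted gene Gm7733 (58.1), Gpr160 (54.4), Cyp1b1 (chromosome 17, 80020709 to 80021128, fold 54.4), Man1c1 (42.2) and the adenylyl cyclase gene Adcy3 (41.3).

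Single-list peaks were weak in both genotypes, with a median log10 q of -3.73 in the control list and -3.20 in the knockout list, against -13.3 and -11.9 for shared peaks. The balance between genotypes changed with the strength of the peak. At q at or under 1e-10, which was chosen after the data were seen and is called strong here, 869 of 9965 control peaks (8.72%, 8.17 to 9.29) had no counterpart among all knockout peaks, and 369 of 9142 knockout peaks (4.04%, 3.64 to 4.46) had none among all control peaks. At q at or under 1e-50, the counts were 129 of 3073 control peaks (4.2%, 3.52 to 4.97) and 14 of 2548 knockout peaks (0.549%, 0.301 to 0.920). Of the 869 strong control peaks without counterpart, 629 (72.4%) lay in genes that had another peak in the knockout list, and 222 of the 369 strong knockout peaks (60.2%) lay in genes with another control peak. The lists were called separately, so a different depth or pull-down efficiency of the libraries moves these shares too.

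**Figure D1:**
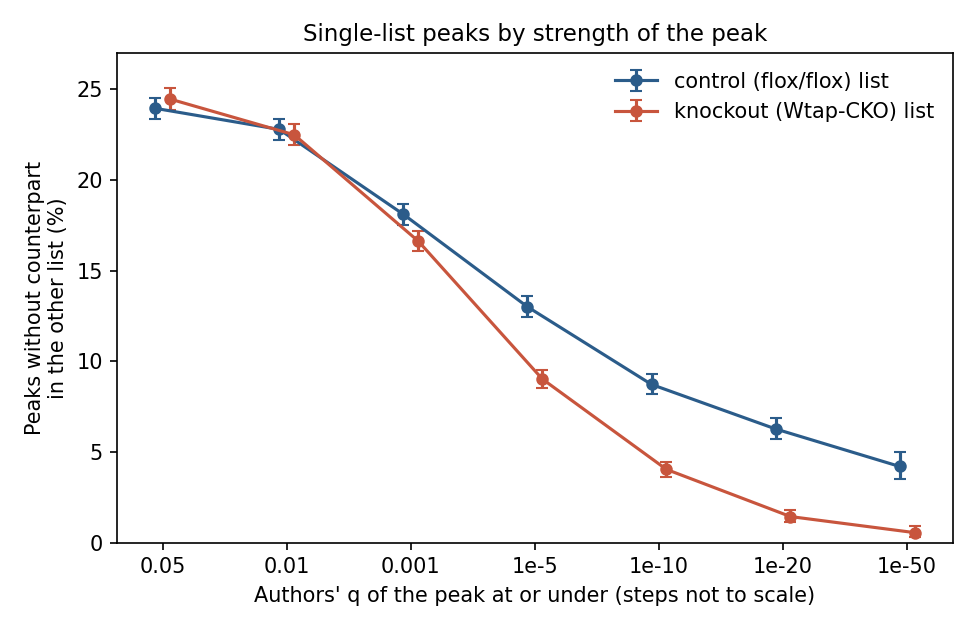
Share of peaks without a counterpart in the other list (y axis, percent) among peaks at or under each q of the authors (x axis, steps not to scale), for the control (blue) and knockout (red) lists, with exact 95% intervals. The shares start at 23.9% and 24.5% and part to 8.72% and 4.04% at q 1e-10.

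The strongest single-list peaks were named after their values were seen. In the control list Popdc2, which encodes a cAMP-binding membrane protein of the heart, led with a peak on chromosome 16 at 38194405 to 38198548 (fold 9.47, log10 p -1660). A peak of Pln, which encodes the SERCA inhibitor phospholamban, followed on chromosome 10 at 53220104 to 53220404 (fold 2.79, log10 p -1440). It lay at the position of a peak of the antisense gene Gm47644, and the calls do not tell these genes apart. Acsl1 (fold 5.89), Mfn2 (6.57), Trim55 (6.68), Pdk4 (8.2) and Ldb3 (5.48) were also among them, each with a log10 q listed as minus infinity. The strongest knockout-only peaks included those of the mitochondrial gene mt-Nd6 (fold 1.60, log10 p -824), Myl2, the ventricular myosin light chain gene (chromosome 5, 122239736 to 122241246, fold 1.90, log10 p -178), the predicted genes Gm10039 (-132) and Gm10221 (-125), Tm4sf1 (-88.0) and Nppb, which encodes brain natriuretic peptide (chromosome 4, 148070332 to 148070534, fold 3.01, log10 p -81.0).

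The third question was which genes carried peaks in each genotype. Of 12182 genes with a peak, 9456 (77.6%, 76.9 to 78.4) had peaks in both lists, 1278 (10.5%, 9.95 to 11%) in the control list only and 1448 (11.9%, 11.3 to 12.5) in the knockout list only. Esrrg, which encodes a nuclear receptor of oxidative metabolism, had 4 control peaks and no knockout peak. Dsc2, which encodes the desmosomal cadherin desmocollin 2, and Hcn2, which encodes a pacemaker channel, had 3 control peaks and no knockout peak. Among knockout-only genes, Wt1, a transcription factor gene of the epicardium, had 2 peaks. When the same number of peaks was taken from each list, the excess of knockout-only over control-only genes went from 170 to -2.

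Of the 25 genes for m6A writers, erasers and readers, 18 had peaks in both lists, 4 in the control list only, none in the knockout list only and 3 (Mettl3, Ythdc2 and Igf2bp1) in neither. Fto, which encodes an RNA demethylase, had a control peak on chromosome 8 at 92135884 to 92168304 (fold 7.57, log10 q -47.7) and no knockout peak. The control-only peaks of Mettl5 (log10 q -1.72), Zcchc4 (-2.64) and Igf2bp3 (-3.80) were weak. Virma, which encodes another subunit of the writer complex, had 7 control and 5 knockout peaks, and Zc3h13 had 5 in each list. Mettl14 had 1 peak in each list, without overlap. Alkbh5, which encodes the other m6A demethylase, kept a shared peak (fold 13.6 in the control, 16.0 in the knockout) and had a control-only peak on chromosome 11 at 60445088 to 60445327 (fold 4.33). Among 10000 random lists matched on peak number, 9.28% had as many control-only genes as this list.

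Of the 25 genes for cardiac transcription factors, 20 had peaks in both lists, 2 (Esrrg among them) in the control list only and 2 (Mef2d and Hand1) in the knockout list only. Mef2a, which encodes a MADS-box factor of muscle, had a control peak on chromosome 7 at 66884566 to 66884955 (fold 2.92, log10 q -38.4), and its knockout peak lay elsewhere, at 67022486 to 67022606, with a log10 q of -1.80. Mef2c kept a shared peak (chromosome 13, 83723669 to 83723849 in the control, fold 2.61) and had a knockout-only peak at 83672985 to 83673165 (fold 18.8, log10 q -5.58). Gata4, which encodes a zinc finger factor of heart development, shared a peak and had a control-only peak on chromosome 14 at 63437533 to 63437980 (fold 3.78, log10 q -64.1) and a knockout-only peak at 63478135 to 63478493 (fold 2.55, log10 q -10.6). Nkx2-5 had 2 shared peaks in each list (highest fold 7.24 in the control and 6.49 in the knockout), and the 3 control peaks of Tbx5 were all shared. Of the strong control peaks in this list, 6 of 28 (21.4%, 8.30 to 41.0) had no knockout counterpart, and 3.29% of random lists matched on strong peaks per gene had as many (4 of 26 and 18% without Esrrg, a count added after the data were seen).

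**Figure D2:**
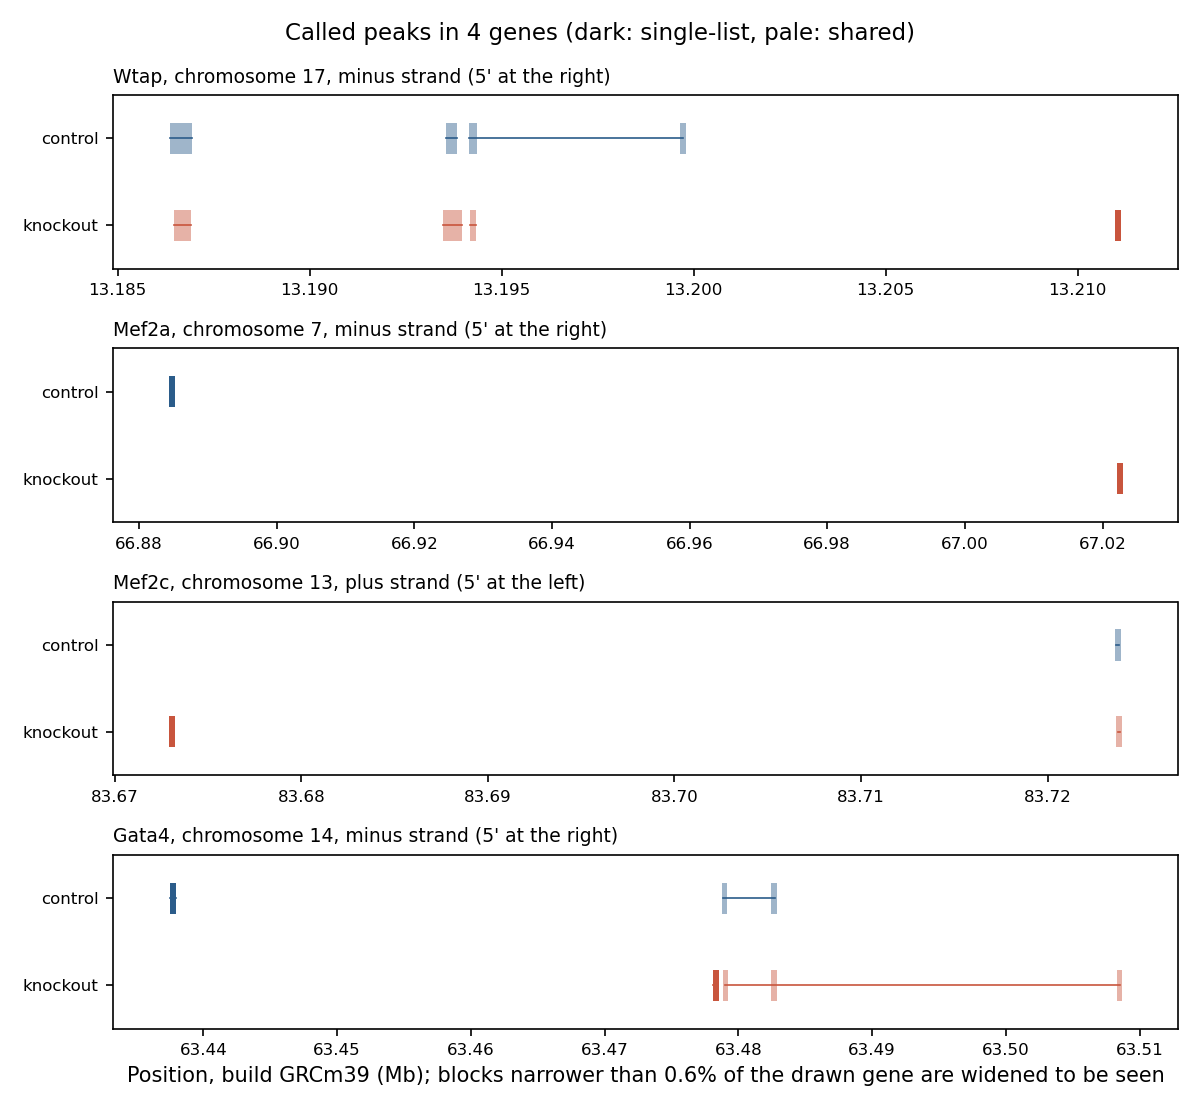
Called peaks of Wtap, Mef2a, Mef2c and Gata4 along each gene's chromosome (x axis, Mb, build GRCm39), with control peaks in blue and knockout peaks in red; boxes are exonic blocks, lines join the blocks of a peak, dark colour marks single-list peaks and pale colour shared ones. The control peak of Mef2a (fold 2.92) and its knockout peak (fold 6.56) lie at different positions.

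Of the 17 genes for cardiac stress and fetal genes, 11 had peaks in both lists, none in the control list only and 4 (Nppb, Acta1, Uchl1 and Mt1, the last named after its values were seen) in the knockout list only. Acta1, the skeletal muscle actin gene that the fetal heart expresses, had a knockout-only peak on chromosome 8 at 124620362 to 124621460 (fold 3.63, log10 q -65.4). Nppa, which encodes atrial natriuretic peptide, had a shared peak with a fold of 3.76 in the control and 3.89 in the knockout. The 3 control peaks of Myh7, which encodes the slow myosin heavy chain, were all shared, and Myh7 had a further, knockout-only peak on chromosome 14 at 55226514 to 55226845 (fold 2.02, log10 q -24.9). Myh6, which encodes the adult mouse myosin heavy chain of the heart, had 5 control and 4 knockout peaks, all of them shared. Of the strong control peaks of the list, 2 of 19 (10.5%, 1.30 to 33.1) had no knockout counterpart, as many as in 42.9% of matched random lists. Of the strong knockout peaks, 3 of 24 (12.5%, 2.66 to 32.4) had no control counterpart, as many as in 3.35% of matched random lists. At q at or under 1e-5 it was 5 of 28 (9% of random lists), and at 1e-20 it was 3 of 19 (0.45%). Without Nppb, 2 of 23 strong knockout peaks had none, as many as in 14.4% of random lists. The count without Nppb was added after the data were seen and was made at the main setting only.

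Strong control peaks without a knockout counterpart were frequent in gene lists for fatty acid oxidation, ion channels and calcium handling. In fatty acid oxidation they made up 13 of 26 strong peaks (50%, 29.9 to 70.1), a count that none of 10000 matched random lists reached. Examples were Acsl1, which activates long-chain fatty acids (3 control peaks and no knockout peak), Cpt2, a mitochondrial carnitine palmitoyltransferase gene (2 and none), and Ppara, the nuclear receptor of fatty acid catabolism (peak on chromosome 15 at 85682445 to 85685792, fold 19.5). In ion channels and conduction they made up 14 of 38 (36.8%, 21.8 to 54.0, 0.08% of random lists), and in calcium handling 12 of 33 (36.4%, 20.4 to 54.9, 0.05%). Ryr2, which encodes the calcium release channel of the sarcoplasmic reticulum, had 6 control and 2 knockout peaks, and Kcnj3 had 4 and 1. Strong here means a small q and not a large fold. These peaks included one of Acsl1 with a fold of 1.63 (log10 q -30.4) and one of Kcnj3 with 46.5 (-50.8). In glycolysis the count was 7 of 20 (35.0%, 15.4 to 59.2, 0.42%), but 4 of the 7 lay in Hk2, a hexokinase gene with 8 control and 3 knockout peaks, and a pair of these overlapped. In sarcomere and Z-disc genes it was 10 of 91 (11%, 5.40 to 19.3, 28.3%). Ttn, the titin gene, had 21 control peaks, of which 4 were shared, and 4 knockout peaks, all shared. In intercalated disc and desmosome genes it was 5 of 23 (21.7%, 7.46 to 43.7, 9.53%). With q at or under 1e-5 in place of 1e-10, the percentage of random lists rose to 6.98% for glycolysis. Counts by gene and without the gene with most such peaks were added after the data were seen. Without Hk2, 3 of 15 strong control peaks of glycolysis genes had no counterpart, as many as in 14.2% of random lists. It was 10 of 23 in fatty acid oxidation without Acsl1 (none of the random lists) and 8 of 28 in calcium handling without Ryr2 (0.59%). The calcium handling count without Ryr2 still held peaks of Slc8a1, named below, at log10 q -278, -137, -88 and -24.3. A count without both genes was not made. In sarcomere genes without Ttn, which held 6 of the 10, it was 4 of 82 (86.2%). When each gene was counted once, 8 of 17 genes with a strong control peak in fatty acid oxidation had one without counterpart (none of the random lists had as many), 9 of 16 in ion channels (none), 6 of 16 in calcium handling (1.80%), 4 of 13 in glycolysis (5.62%) and 5 of 19 among cardiac transcription factors (5.53%).

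Other genes on these lists with strong control-only peaks, named after their values were seen, were Slc8a1, the sodium-calcium exchanger gene (chromosome 17, 81956603 to 81977475, fold 6.84, log10 q -278), Kcne1, which encodes a potassium channel subunit (chromosome 16, 92145191 to 92145577, fold 3.70, log10 q -188), and Gja1, the connexin 43 gene (chromosome 10, 56266162 to 56266462, fold 2.69, log10 q -138). Of strong knockout peaks, none of 19 in ion channels, 1 of 26 in calcium handling, 4 of 87 in sarcomere genes and 1 of 19 in intercalated disc genes had no control counterpart. In fatty acid oxidation it was 3 of 19 (15.8%, 3.38 to 39.6, 4.01% of random lists) and in glycolysis 2 of 13 (15.4%, 1.92 to 45.4, 10.4%). Over all genes the share was 4.04%. At q at or under 1e-20, 0 of 11 knockout peaks of fatty acid oxidation genes lacked a control counterpart.

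In gene lists of other heart cell types, few strong control peaks lacked a knockout counterpart. None of 34 strong control peaks in fibroblast and matrix markers, of 29 in endothelial and endocardial markers, of 25 in smooth muscle and pericyte markers, of 5 in immune cell markers or of 2 in epicardial and neural markers lacked a knockout counterpart, and 1 of 5 in erythroid markers did, in Ank1, which encodes ankyrin 1. Each of these lists is short, and counts of 0 as low were reached by 6.54%, 9.62%, 17.4%, 64.2% and 85.2% of matched random lists for the first 5. At q at or under 1e-5 these counts were also 0, and the percentages were 0.61%, 2.01%, 3.65%, 35.6% and 67.7%, in the same order. At q at or under 1e-20 they were 0 again, and the percentages were 20.3%, 28.0%, 38.9%, 83.7% and 94.5%. In the knockout list, 6 of 49 strong peaks of fibroblast and matrix markers (12.2%, 4.63 to 24.8, 0.47% of random lists) and 4 of 38 of endothelial markers (10.5%, 2.94 to 24.8, 6.44%) had no control counterpart. The collagen gene Col1a2 (chromosome 6, 4505640 to 4505880, fold 18.8) and Pecam1, an adhesion gene of endothelium (chromosome 11, 106545672 to 106545941, fold 2.59), were among them and were chosen after their values were seen. In smooth muscle markers it was 1 of 29 (58.2% of random lists), in immune markers 1 of 8 (33.2%), in erythroid markers none of 4 and in epicardial and neural markers none of 3.

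The lists for the sarcomere, calcium handling, ion channels and fatty acid oxidation, called heart muscle lists here, and those for other cell types were then joined, which was also decided after the data were seen, leaving out 2 genes that stood in both groups. In the heart muscle lists, 49 of 185 strong control peaks (26.5%, 20.3 to 33.5) had no knockout counterpart, and 42 of these 49 lay in genes with another knockout peak. The 49 peaks lay in 28 genes, while the interval takes each peak as independent, so it can be too narrow. Without Ttn the count was 43 of 176 (24.4%, 18.3 to 31.5). With the lists for cardiac transcription factors, stress and fetal genes and the intercalated disc added, it was 61 of 246 (24.8%, 19.5 to 30.7), and without fatty acid oxidation 48 of 220 (21.8%, 16.5 to 27.9). In the 6 lists of other cell types it was 1 of 97 (1.03%, 0.0261 to 5.61), against 8.72% over all genes. Strong knockout peaks without a control counterpart made up 8 of 148 (5.41%, 2.36 to 10.4) in heart muscle lists and 12 of 128 (9.38%, 4.94 to 15.8) in the lists of other cell types, against 4.04% over all genes. RNA levels in the input libraries were not analysed here.

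**Figure D3:**
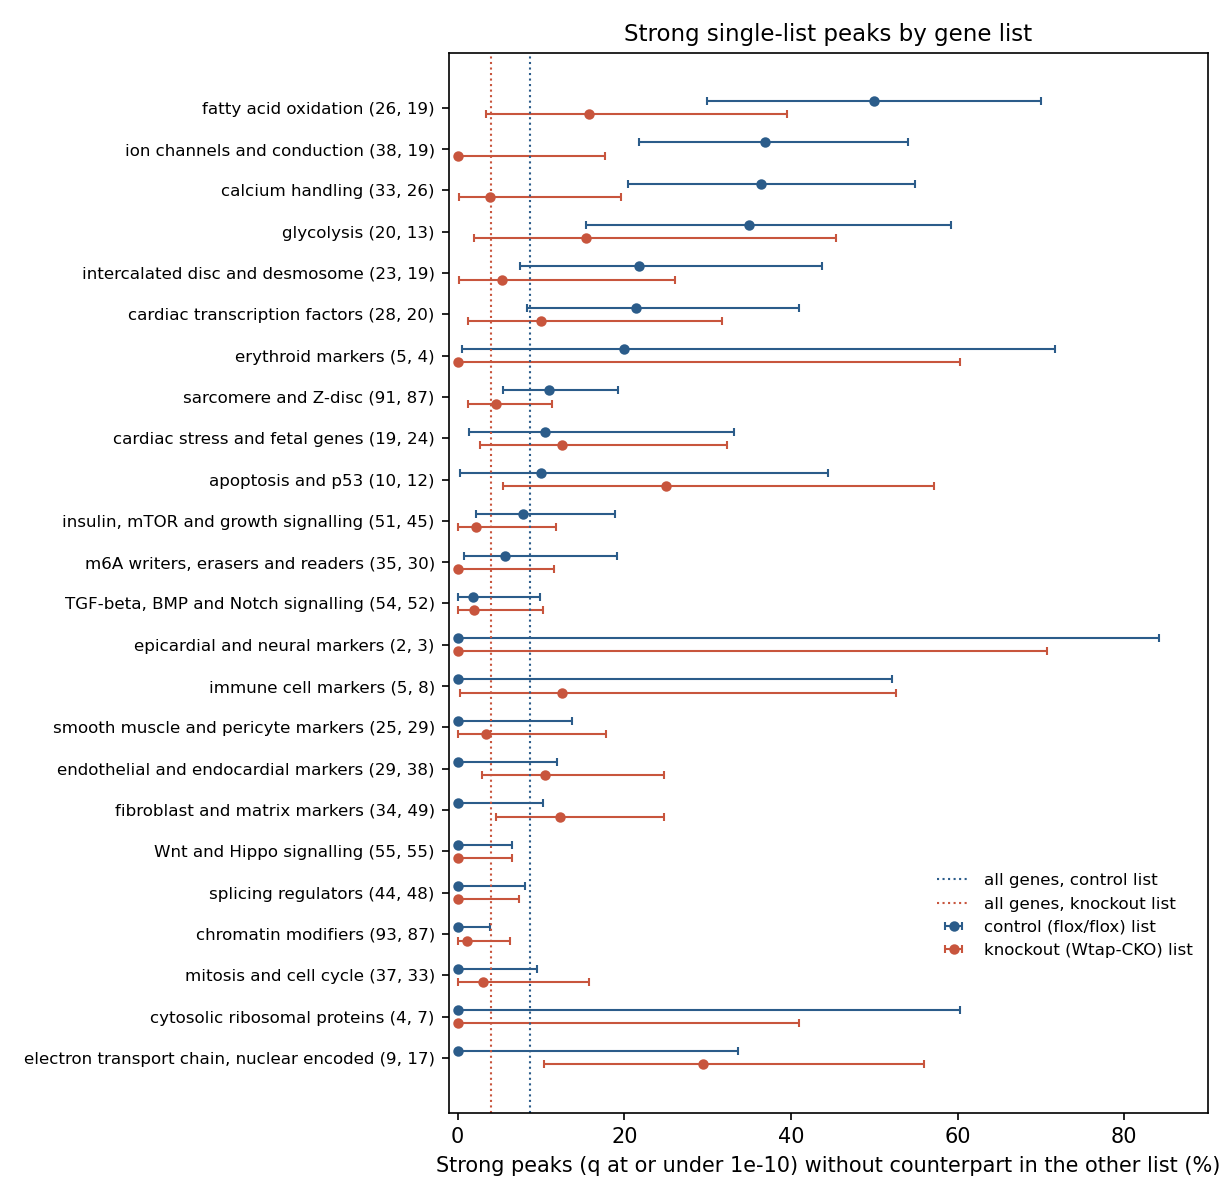
Strong peaks (q at or under 1e-10) without a counterpart in the other list (x axis, percent of the list's strong peaks) for 24 gene lists (y axis, number of strong control and knockout peaks in brackets), with exact 95% intervals; blue is the control list, red the knockout list, and dotted lines mark all genes. Control peaks reach 50% in fatty acid oxidation and 0% in fibroblast, endothelial and smooth muscle markers.

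Lists of chromatin, Wnt, splicing and mitosis genes held no strong control-only peak. None of 93 strong control peaks in chromatin modifiers lacked a knockout counterpart, and 0.12% of random lists were as low; none of 55 did in Wnt and Hippo signalling (1.67%), none of 44 in splicing regulators (3.80%) and none of 37 in mitosis and cell cycle genes (6.61%). At q at or under 1e-5, 5 of 124, 4 of 82, 5 of 54 and 3 of 48 control peaks of these lists had no counterpart. The percentages of random lists as low were 0.37%, 2.94%, 32.2% and 15.45%, in the same order. At 1e-20 none of their peaks lacked a counterpart, and the percentages were 1.47%, 6.38%, 13.3% and 22.2%. Only chromatin modifiers stayed under 5% at each setting. The lysine methyltransferase gene Kmt2d had 11 peaks in each list, of which 8 were shared, and the splicing gene Son had 9 in each. Fat4, an atypical cadherin gene, had 11 control and 13 knockout peaks, and the proliferation marker gene Mki67 had 10 and 8. In TGF-beta, BMP and Notch signalling 1 of 54 strong control peaks had no counterpart, in Bmp10, which encodes a growth factor of the heart (fold 23.7, log10 q -43.0, no knockout peak). In insulin, mTOR and growth signalling it was 4 of 51, and in m6A writers, erasers and readers 2 of 35. In the knockout list, none of 55 strong peaks of Wnt and Hippo genes, none of 48 of splicing regulators, none of 30 of the m6A list and 1 each of 87 in chromatin modifiers, 33 in mitosis, 52 in TGF-beta and 45 in insulin signalling genes had no control counterpart.

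Counted by gene, genes for electron transport and ribosomal proteins carried peaks in the knockout list only more often than in the control list only. Of 36 nuclear genes for electron transport, 14 had peaks in both lists, 2 (Ndufa2 and Cycs) in the control list only and 10 in the knockout list only, among them Cox5b (fold 4.79) and Cox6c (3.15). Of 43 genes for cytosolic ribosomal proteins, 10 had peaks in both lists, 1 (Rps18) in the control list only and 7 in the knockout list only, among them Rps23 (fold 24.4) and Rps14 (20.6). As many knockout-only genes were found in 9.46% and 6.44% of random lists matched on peak number and in 0.11% and 0.23% of unmatched ones. Of strong knockout peaks in electron transport genes, 5 of 17 (29.4%, 10.3 to 56.0, 0.18% of random lists) had no control counterpart, and none of 9 strong control peaks lacked a knockout one. At q at or under 1e-5, 8 of 20 knockout peaks of these genes (40%, 19.1 to 63.9, 0.09% of random lists) lacked a control counterpart. At 1e-20 none of 9 did. In ribosomal protein genes, none of 7 strong knockout peaks and none of 4 strong control peaks lacked a counterpart.

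In the remaining lists, single-list genes were few. Intercalated disc and desmosome genes had 3 control-only members (Dsc2, Ctnna3 and, named after its values were seen, Dsg2) and 1 knockout-only member (Emd). The count of 3 was reached by 2.53% of matched random lists but by 28.2% of unmatched ones. Ion channels had 2 control-only members (Hcn2 and Kcnd2) and none in the knockout only. Epicardial and neural markers had 3 knockout-only members (Wt1, Krt8 and, named after its values were seen, Krt18, 2.99% of matched random lists), immune markers 4 and no control-only member, calcium handling genes 4 against 1 control-only, apoptosis and p53 genes 4 against 1, and fibroblast, smooth muscle and erythroid markers 2 each against none. Mitosis genes had 3 knockout-only and 1 control-only members, and splicing regulators 2 and 1. Fatty acid oxidation genes had 2 of each kind, and glycolysis, chromatin and TGF-beta genes had 1 of each. Sarcomere genes had 1 knockout-only member (Acta1), Wnt and insulin signalling had 1 control-only member each (Tcf7l2 and Erbb3), and all 24 endothelial markers had peaks in both lists. In all, 13 of the 24 lists had more knockout-only and 5 more control-only members, and 48 such percentages were computed, so a few below 5% arise by chance.

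Single-list peaks were also placed along their genes, a comparison added after the data were seen. Of control-only peaks that lay outside all shared peaks of their gene, 977 of 2275 (42.9%, 40.9 to 45.0) lay 5' of them, and of such knockout-only peaks 1698 of 2561 (66.3%, 64.4 to 68.1) did. Among strong peaks the counts were 88 of 416 (21.2%, 17.3 to 25.4) and 106 of 175 (60.6%, 52.9 to 67.9). Gata4 and Mef2c were examples, with a control-only peak of Gata4 at 63437533 on the minus strand, 3' of its shared peak as was its knockout-only peak, and a knockout-only peak of Mef2c at 83672985 on the plus strand, 5' of its shared peak. The knockout-only peak of Wtap at 13210995 on the minus strand also lay 5' of its shared peaks.

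**Figure D4:**
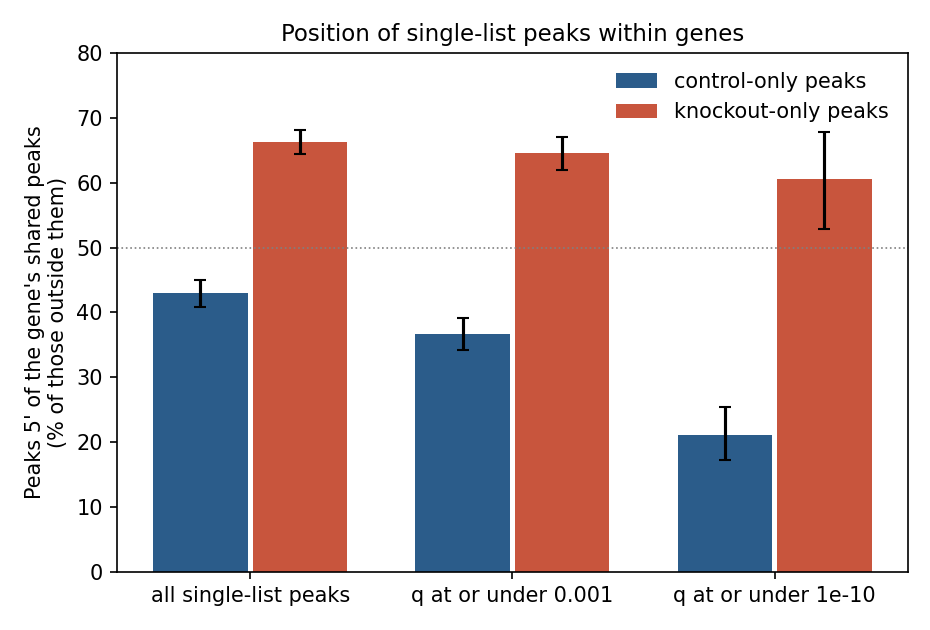
Share of single-list peaks that lie 5' of all shared peaks of their gene (y axis, percent of those outside the shared peaks), for all single-list peaks and those at q at or under 0.001 and 1e-10, with exact 95% intervals; blue is control only, red knockout only. The shares were 42.9% and 66.3% over all peaks, and 21.2% and 60.6% among strong peaks.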

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

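The settings at q 1e-5, 1e-10 and 1e-20 were chosen after the data were seen. So were the joined lists (4, all 7, or 6 without fatty acid oxidation), the counts by gene or without 1 gene, and the positions along genes. The other settings were chosen before the data were examined. No paired analysis was possible because each genotype had 1 pooled IP and input pair. The excess of knockout over control peaks (413) was 249 at q at or under 0.01 and 2 at 0.001, and turned to -5 at a fold of at least 4. The excess of knockout-only over control-only peaks (207) was 405 with an overlap of 50% of both peaks and 42 at q 0.01. It turned to -201 at q 0.001 in both lists, to -169 with the same number of peaks, and, when peaks of a list were sought among all peaks of the other, to -257 at q 0.001, -592 at 1e-5, -500 at 1e-10 and -329 at 1e-20. The cause was not tested. The excess of knockout-only genes (170) was 108 at q 0.01 and turned to -2 with the same number of peaks.

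Control-only peaks numbered 7996 with an overlap of 50% of both peaks and, by construction fewer, 3148, 1791, 869 and 413 among peaks at q 0.001, 1e-5, 1e-10 and 1e-20. Knockout-only peaks numbered 8401, then 2891, 1199, 369 and 84, and 3408 with the same number of peaks. Shared control peaks numbered 9096 at 1e-10 and 6177 at 1e-20. The median fold was 7.62 for shared, 7.36 for q 0.001 and 8.82 for 1 peak per gene in the control list, and 7.27 and 8.82 for the last 2 in the knockout list. At q 0.01, 8 lists in place of 5 had more control-only members. The other 65 values of these results were counted as unchanged, as were 1249 of the values for single genes and list members, while 155 of the latter moved. Unchanged did not mean equal. Control-only peaks numbered 3577 in place of 4973 with the same number of peaks. Control peaks with a fold of at least 4 numbered 15494 in place of 20766. With the same number of peaks, 7 lists in place of 5 had more control-only members. Of 48 list percentages, 4 changed sides of 5% without matching: intercalated disc genes rose to 28.2%, and electron transport (0.11%), ribosomal protein (0.23%) and immune genes (2.95%) fell below it. Transcript regions, motifs and matching on exonic length were not run, for want of the genome and annotation of the files' build. Depth, unknown here, limits what a peak missing from a list can show.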

Other observations

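The all-gene comparison for ribosomal and electron transport genes, the random lists for heart muscle genes and the comparison with other cell types were tests chosen after their results had been seen, and strong peaks and positions along genes were defined after the data were seen.

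Pseudogenes were more often in the knockout list only (142) than in the control list only (47), while lncRNA genes were more often in the control list only (126 against 76). Knockout-only peaks of genes outside the fixed lists, named after their values were seen, were strong in Tm4sf1, which encodes a tetraspanin-like membrane protein (chromosome 3, 57202114 to 57202443, fold 5.86, log10 q -86.0), in Atpif1, which encodes an inhibitor of the mitochondrial ATP synthase (fold 2.12, log10 q -67.7), and in Laptm4a (chromosome 12, 8971959 to 8972255, fold 19.7, log10 q -56.3). In apoptosis and p53 genes, 3 of 12 strong knockout peaks (25%, 5.49 to 57.2, 2.35% of matched random lists, and 7.71% without Bax, where 2 of 9 remained) had no control counterpart (none of 8 at q at or under 1e-20), among them those of Casp8 and Bax, against 1 of 10 strong control peaks, in Bcl2l11. The apoptosis genes and the glucose transporter genes were also named after their values were seen. Slc2a1 had a strong knockout-only peak (fold 8.31), and Slc2a4 had a control-only peak at 69834114 to 69834354 and a knockout-only peak at 69838804 to 69839014 on chromosome 11.

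Strong control peaks without a knockout counterpart were rare in lists of other cell types and common in fatty acid oxidation, ion channel and calcium handling genes, but in sarcomere, cardiac stress and intercalated disc genes together they made up 8.85% (4.33 to 15.7) without Ttn, as many as in 49.1% of matched random lists. The 6 heart lists other than fatty acid oxidation, joined after the data were seen, held 48 such peaks (101 genes). More strong peaks per gene do not account for this number, since 0 of 10000 random lists matched on them held as many (median 19). None held as many as the 42 left without Ttn either. The 6 lists include the ion channel and calcium handling lists that prompted the pattern, so the result gives no further support for it. An equal loss in all cell types stays open, because the 1.03% (0.0261 to 5.61) in other cell types, against 8.72% over all genes, is part of the pattern, and none of 93 strong control peaks of chromatin modifiers, a list of no cell type, lacked a counterpart either. A lower level of heart muscle transcripts in the knockout RNA stays open: over shared peaks of like fold and width, the median log2 ratio of log10 p (knockout over control) differed by 0.10 (-0.25 to 0.24) between heart muscle and all other genes, which met the bound set against it, but only 2 of the 28 genes with a lost strong peak had such a peak, so the bound was set on genes that do not carry the pattern. Loss of m6A in the cells in which Wtap was deleted, which the labels do not name, was not tested, and the depth and pull-down efficiency of the libraries, confounded with genotype, stay open as well.

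Knockout-only peaks lay 5' of the shared peaks of their gene more often than control-only peaks. The shares of 66.3% and 42.9% define the pattern and so give no test of an even scatter. Single-list peaks that were themselves near the threshold were excluded as the whole cause, since the share was 64.5% against 36.6% at q at or under 0.001. A counterpart that just missed the threshold of the other list still counted as absent, so that part stays open. Wider detection at the 5' end of every transcript is undecided, as the share was 56.3% (50.5 to 62.0) in genes with a control-only peak 3' of the shared ones and 67.6% in genes without, an outcome that neither prediction named. A shift of coverage along transcripts of all cell types is undecided too, with 55.2% (35.7 to 73.6, 29 peaks) in lists of other cell types, an interval that covers both shares; control-only peaks there gave 3 of 5, and in heart muscle lists the intervals of 8 of 16 knockout-only (50%, 24.7 to 75.3) and 16 of 42 control-only peaks (38.1%, 23.6 to 54.4) overlapped, so these groups were too small to separate the shares.

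Ribosomal protein and electron transport genes carried peaks in the knockout list only more often than in the control list only. Their 20 single-list genes, 85.0% of them knockout-only, prompted the pattern and so give no test. The choice of list members was excluded as the whole cause by members of the same families on neither list. These members were taken by the start of their symbols alone, such as Rpl, Rps, Ndufa or Cox. Of their 16 single-list genes, 15 were knockout-only (93.8%, 69.8 to 99.8), against 53.1% over all genes. For more calls in the knockout list for all genes, these same values were used. That comparison was chosen after its result had been seen, so it is no separate test. Calls near the threshold stay open. At q at or under 0.001, 91.2% (76.3 to 98.1) of 34 single-list family members were knockout-only, against 50.4% over all genes. That share met the bound set against this cause, but it counts listed and unlisted members together, so it is no separate test. Reads shared with pseudogene copies, RNA levels and library depth were not tested and stay open. With random lists matched on peak number, 9.46% and 6.44% held as many knockout-only genes as the electron transport and ribosomal lists. At equal peak number neither count of knockout-only genes thus stood apart at 5%. Control-only genes numbered 2 and 1, against medians of 6 and 4, and 99.5% and 98.8% of these random lists held as many. A gene with 1 peak in both lists together is single-list by construction, so this matching is not independent of the outcome.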
